A study of Mus musculus with 12 samples.

How the data were processed

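The study measured RNA in perigonadal adipose tissue of mice labelled female, aged 6 months and fed ad libitum, on 12 Affymetrix arrays, 1 per mouse. Per the labels, total RNA was extracted with a Qiagen RNeasy kit, labelled with biotin and hybridised at a core facility. The 4 groups hold 3 mice each and were taken from the sample titles, since the genotype field gives control animals the same value as the mutants of their line. The overexpressor carries a Glut4 transgene under the aP2 promoter and was set against littermates on the FVB background. The adipose knockout was set against animals carrying aP2-Cre, both on a mixed C57B6, FVB and SV129 background.

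The deposited values are intensities, 1 per probe set and array, on a linear scale. The summarisation software, scaling and background treatment behind the deposited intensities are not given in the sources used here. The smallest deposited intensity was 21.9 on each of the 6 arrays of the overexpressor line and 22.27 on each of the 6 of the knockout line, with 4.84% to 5.29% of values at that floor. The table therefore appears to join 2 sets of 6 arrays processed separately, so no level is compared between the lines, and each mutant is read only against its own control. Across probe sets, an array's log2 values had a mean correlation of 0.948 to 0.973 with the other arrays of its group, of 0.946 to 0.971 with the opposite group of its line and of 0.773 to 0.809 with those of the other line. Closer to the opposite group than to their own were overexpressor control 3 (0.971 against 0.954), knockout 1 (0.963 against 0.960), knockout control 1 (0.959 against 0.957) and knockout control 2 (0.961 against 0.956). The largest value was 8944.59. Median intensity per array ran from 185.8 (knockout control 3) and 188.1 (overexpressor 1) to 219.4. No 2 columns were identical, and the smallest root mean square log2 difference between arrays of a group was 0.187, so every array counted as 1 replicate. An array gives no read depth, and the number of arrays limits the precision. Control probe sets were not used here, so the planned 3' to 5' ratio of RNA quality was not computed.

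Values were transformed as log2(intensity + 36.92), the constant being the 10th percentile of the table. Log2 fold changes are on this scale and understate the changes of dim probe sets. Array medians spanned 0.20 on it, under the limit of 0.5 set for normalizing again, so the deposited intensities were used without further normalization. Of 12422 probe sets, the 4968 (40%) with the lowest mean over all 12 arrays were left out, and 7454 were tested. Group means of all 12 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 8 residual and 4.32 prior degrees of freedom). The contrasts were overexpressor minus its control, knockout minus its control, and the difference between those effects. P-values were adjusted by Benjamini-Hochberg over the tested probe sets, with a threshold of 0.05. An exact permutation test of 3 against 3 cannot give a two-sided p below 0.1, so no single-gene permutation test was used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

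Gene names came from the platform annotation. It gave 1 symbol to 10833 probe sets, several to 396 and none to 1193, and 10817 of the first kind matched a gene of the reference annotation by gene ID, which updated old symbols. The reference assembly, GRCm38.p6, served only for names and for which genes neighbour each other, and no coordinates are given because the array names no build. Probe sets with several symbols are given by their identifier. For each of 5706 tested genes, the probe set with the highest mean over 12 arrays stood for the gene.

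Design, alternatives, gene lists and the rule for named genes were fixed before the data were examined, apart from the choices that are said below to have been made later. There were 37 lists of pathways and of cell types that such a tissue sample could hold. Of the list entries, 569 were tested, 141 were dim and 180 were not named by a probe set with a single gene. Lists were tested with limma's camera, which compares a list with all other genes, using a preset correlation of 0.01 between genes, then with an estimated correlation, and with fry (directional, and mixed). The limma p-values of members were also adjusted over each list alone, which does not correct for the number of lists. The lists for lipogenesis, branched-chain amino acids, nicotinamide and retinoids were chosen with knowledge of reports on these mouse lines, possibly on these arrays, so their direction is not independent evidence. Named genes were Slc2a4, up to 10 called genes per direction with groups that did not overlap (or, where none was called, the 5 with the smallest p), up to 3 members per list with the smallest p plus others needed to show direction, genes past the threshold in both comparisons or in the difference, and a fixed set of adipose genes. Of that set, Mlxipl and Acaca were not named by a probe set with a single gene, and Ccl2 was dim.

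On simulated data with known changes in the overexpressor comparison, limma called 42.0% of 69 probe sets changed by 0.5 on the log2 scale, 91.9% of 62 changed by 1 and 100% of 69 changed by 2, and 4.91% of calls were false. In the simulated knockout comparison the shares were 32.9% of 70, 98.4% of 64 and 100% of 66, with 3.80% of calls false. A simulated list shift was found with both camera settings, and 0 of 36 unshifted lists were called. The simulated genes varied independently of each other, while genes of real lists varied together between mice. The simulated shares of false calls therefore do not give the error rates on these arrays. Nor do the shares of changes found carry over to them. The simulations called 163 and 158 probe sets, against 6 and 9 in the real overexpressor and knockout comparisons. The Benjamini-Hochberg cut on p is stricter where fewer are called, so real changes of these sizes can be missed more often. The alternatives covered the constant added before the log, quantile and median normalization, the filter on dim probe sets, the variance trend, array weights, the replicate number as a block, fits on each line's own arrays, each array left out in turn, other thresholds, 1 probe set per gene, and other list tests.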

Results

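Perigonadal fat of 12 mice labelled female was profiled to compare gain and loss of the insulin-responsive glucose transporter Glut4, encoded by Slc2a4, in adipose tissue. There were 3 overexpressors with 3 controls and 3 knockouts with 3 controls, each mouse on its own array. Values are array intensities, given as mean ± SD (n = 3 arrays), with log2 fold changes, standard errors (SE) and limma's Benjamini-Hochberg adjusted p over 7454 probe sets. The number of arrays limits their precision.

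The target gene was examined first. On the arrays labelled overexpressor, the Slc2a4 probe set read 624.6, 1110 and 1042, and on their controls 639.0, 582.7 and 1212. The log2 fold change was 0.22 (95% interval -0.35 to 0.78, limma adjusted p = 0.930), so the main fit detected no rise of Slc2a4 on these arrays. The planned array weights, whose iteration did not converge, did call a rise, and gene-by-gene weights did not. The knockouts read 377.5, 365.4 and 363.4 and their controls 416.1, 513.5 and 614.2. All 3 knockouts lay below all 3 controls, but 566 of 7454 tested probe sets (7.59%) separated these groups completely, in either direction. The log2 fold change of -0.43 (95% interval -0.99 to 0.14) did not pass the test. A second Slc2a4 probe set stayed between 21.9 and 33.2 on all arrays and was too dim to test. The labels state neither the deleted exons nor the species of the transgene, so these probe sets may not read either change, and they check neither set of labels.

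**Figure D1:**
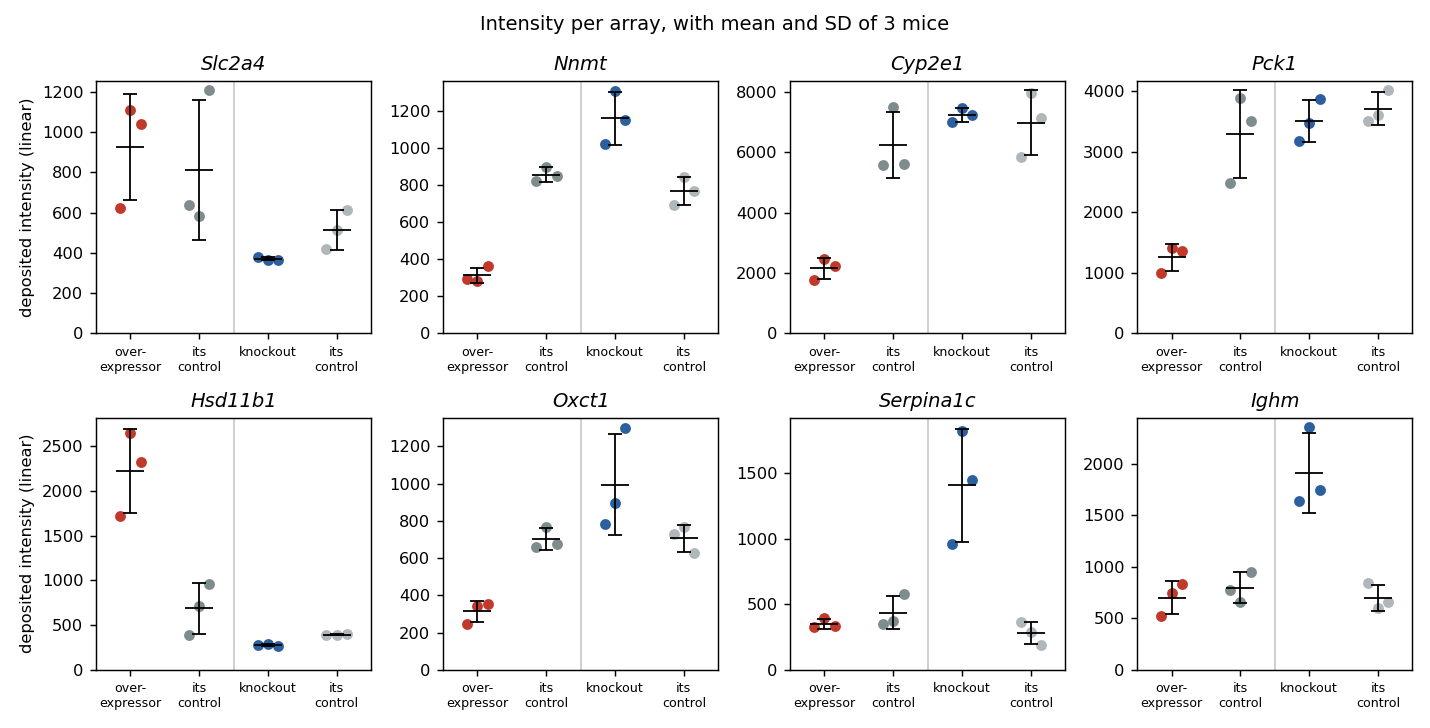
Deposited intensity (linear axis from 0) of 8 genes on each array, with the mean and SD of 3 mice per group; the line divides the array sets, whose levels are not compared. Nnmt, Cyp2e1 and Pck1 lay lower on all 3 overexpressor arrays than on their controls, Serpina1c and Ighm lay higher on all 3 knockout arrays, and the Slc2a4 values of overexpressors and controls overlapped.

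What Glut4 overexpression changed in fat was the question of the first comparison. Fat of the overexpressors had less mRNA of 3 abundant metabolic genes. Nnmt, which methylates nicotinamide, read 311 ± 43.2 against 856 ± 39.7 in controls (log2 fold change -1.37, SE 0.13, limma adjusted p = 0.00113). Cyp2e1, a cytochrome P450 that oxidises small molecules, fell from 6226 ± 1096 to 2150 ± 348 (-1.52, SE 0.16, adjusted p = 0.00147). Pck1, the cytosolic phosphoenolpyruvate carboxykinase, fell from 3293 ± 730 to 1256 ± 221 (-1.36, SE 0.17, adjusted p = 0.00768). Hsd11b1, which regenerates active glucocorticoid, rose from 686 ± 287 to 2229 ± 471 (1.71, SE 0.25, adjusted p = 0.0213).

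The 2 remaining calls were Mmp12 and Mup3. A probe set for Mmp12, a macrophage elastase, read 352 ± 68.0 against 128 ± 18.1 (1.23, SE 0.14, limma adjusted p = 0.00200); it is not the probe set that stands for the gene and is named here after its values were seen. The brighter Mmp12 probe set changed by 1.03 and did not pass. Mup3, of the major urinary protein family, read 32.3 ± 14.9 against 109 ± 13.7 (-1.09, SE 0.16, adjusted p = 0.0245), near the floor, and its other probe set changed by -0.23. Its overexpressor mean lies below the constant of 36.92 added before the log, so the size of the change depends on that constant, at -1.80 with a constant of 1 and -0.73, without a call (adjusted p = 0.0713), with the 25th percentile; related family members can share probes. Oxct1, the enzyme that lets tissues use ketone bodies, read 313 against 701 and missed the threshold (-1.09, adjusted p = 0.0557). In all, 6 of 7454 probe sets were called (2 higher, 4 lower), and 355 had an unadjusted p under 0.05 (92 higher, 263 lower), against 373 that chance gives. With array medians subtracted 11 were called (6 higher, 5 lower), and with quantile normalization 12 (6 higher, 6 lower).

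Nnmt and Cyp2e1 stayed called whichever single array was left out. On the overexpressor line's own 6 arrays limma called Nnmt alone (adjusted p = 0.0245), and the calls of Cyp2e1 (0.0678), Pck1 (0.128), Mup3 (0.128), Hsd11b1 (0.278) and Mmp12 ended. In the fit of all 12 arrays, the call of Pck1 ended without overexpressor control 2 (adjusted p = 0.0617), that of Hsd11b1 without overexpressor control 2 (0.0846), overexpressor 2 (0.124) or overexpressor 3 (0.125), and that of Mup3 without overexpressor 1 (0.0973), overexpressor 3 (0.149), overexpressor control 1 (0.127), overexpressor control 2 (0.197) or knockout 2 (0.0515). Without a filter on dim probe sets Hsd11b1 and Mup3 were not called (adjusted p = 0.0973 for each), nor was Mup3 without the 2 dimmest arrays (0.183).

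Genes of fatty acid synthesis lay higher in the overexpressors. Of 12 tested members of the lipogenesis list, 11 were higher, with a median log2 change of 0.29, and the list was called by camera (adjusted p = 1.10e-06; adjusted p = 0.915 with an estimated correlation). This list and the branched-chain one were chosen with knowledge of reports on these lines, so their direction is not independent evidence. No member passed over all genes. Elovl6, which elongates palmitate, read 2813 against 864 (1.89) and was the 1 member called when p was adjusted over the list alone (adjusted p = 0.0313). Adjustment over a list alone, here and below, does not correct for the 37 lists tested in each comparison. Acly, which makes cytosolic acetyl-CoA, was at 0.59, Fasn, the fatty acid synthase, at 0.35, Thrsp at 0.50 and Scd1 at 0.10. The pentose phosphate list, which supplies NADPH, was also called, with 5 of 8 members higher (median 0.27, adjusted p = 0.0121; adjusted p = 0.915 with an estimated correlation). Its members Tkt (0.71), Pgd (0.41) and H6pd (0.32) did not pass, alone or over the list. Without overexpressor control 2, the array with the lowest lipogenic mean of its group, the lipogenesis median was 0.094 and its adjusted p 0.0516, with Acly at 0.092 and Fasn at 0.15. The median was 0.17 without overexpressor 2, 0.18 without overexpressor 3, 0.45 without overexpressor 1 and 0.52 without overexpressor control 3. Acly was at 0.92 without overexpressor control 3, and Scd1 at 0.15 without overexpressor 1. The pentose phosphate call ended without overexpressor control 2 (median 0.093, adjusted p = 0.0869), overexpressor 2 (0.13, 0.0985) or overexpressor 3 (0.20, 0.0769), and its median was 0.18 without overexpressor control 1; it also ended without a filter on dim probe sets (0.0553). With array weights the lipogenesis median was 0.76.

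The lists of branched-chain amino acid breakdown and fatty acid oxidation lay lower. In branched-chain amino acid breakdown, 14 of 15 members were lower (median -0.29, camera adjusted p = 0.00337; adjusted p = 0.915 with an estimated correlation). Adjusted over the list alone, 3 passed: Bcat2, the mitochondrial aminotransferase (-1.02), Mccc1 (-0.94) and Ivd (-0.59), both of leucine breakdown; over all genes, 0 did by limma, and the same 3 had an unadjusted p under 0.05. Fatty acid oxidation had 18 of 21 members lower (median -0.25, adjusted p = 0.0498; adjusted p = 0.915 with an estimated correlation), with Cpt2 at -0.49. That list lost its call (adjusted p 0.0565 to 0.661) without overexpressor 1 or 3, overexpressor control 2 or 3, knockout 2 or 3 or knockout control 3, and the branched-chain list lost it without overexpressor 1 (adjusted p = 0.156) or overexpressor control 3 (0.274). The fatty acid oxidation call also ended without a filter on dim probe sets (0.0899), with the lowest 60% left out (0.0990), with a larger constant before the log (0.0537), with array weights (median -0.15, 0.154) or gene-by-gene weights (-0.13, 0.240) and without the 2 dimmest arrays (0.663), and its median was -0.15 with quantile normalization. The branched-chain call ended with array weights (0.0691), gene-by-gene weights (median -0.19, 0.0834) or without the 2 dimmest arrays (0.171). Both medians shrank most without overexpressor 1, to -0.042 for fatty acid oxidation and -0.11 for branched-chain amino acid breakdown. Cidec and G0s2, proteins of the lipid droplet, were called over their list alone (-0.77 and -0.80), while their list was not (median -0.20, adjusted p = 0.239) and its median was 0.036 without overexpressor 1.

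**Figure D2:**
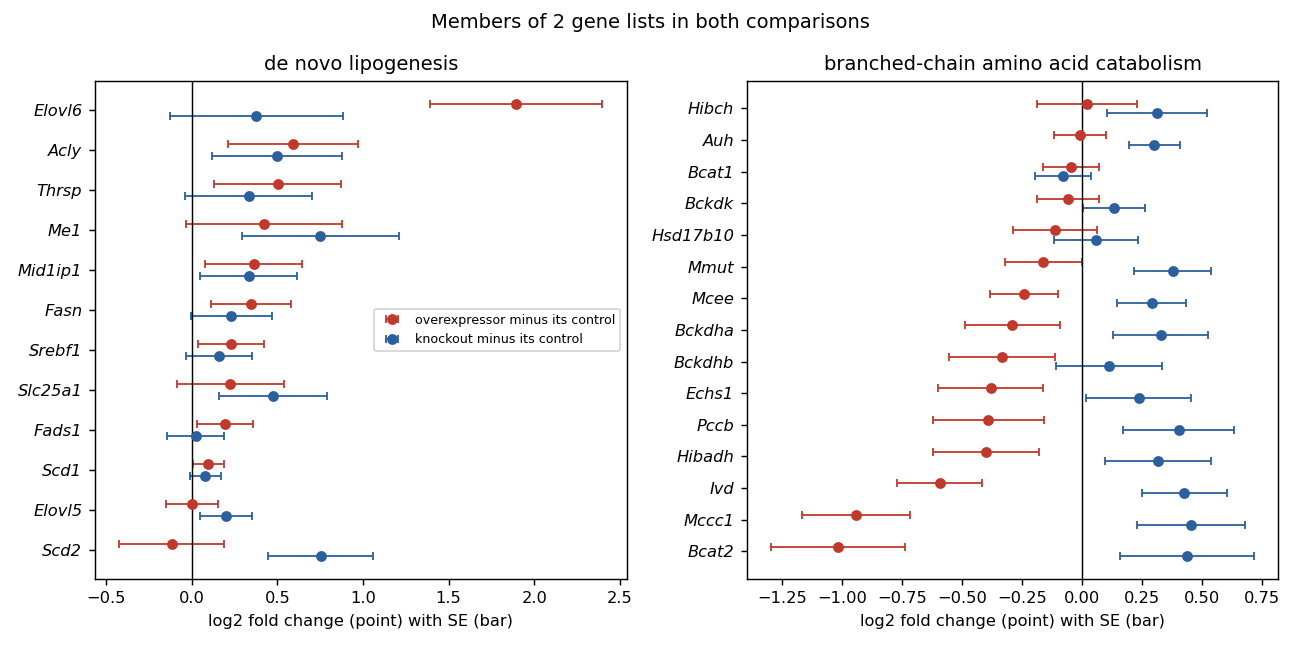
Log2 fold change (point) with its SE (bar) of each tested member of 2 lists, overexpressor minus its control and knockout minus its control. In lipogenesis 11 of 12 members were above 0 in the overexpressor and 12 of 12 in the knockout; in branched-chain amino acid breakdown 14 of 15 were below 0 in the overexpressor and 14 of 15 above 0 in the knockout.

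Stromal genes lay lower as well. The matrix and fibroblast list had 31 of 34 members lower (median -0.43, camera adjusted p = 1.46e-07; adjusted p = 0.915 with an estimated correlation), among them Dpt (-0.77), Postn (-0.66) and the type I collagen gene Col1a2 (-0.62), with Thbs2 at 0.68. None of these passed over all genes or adjusted over the list alone, and 14 had an unadjusted p under 0.05 (1 higher, 13 lower). Smooth muscle and pericyte markers were lower in 11 of 12 (median -0.40, adjusted p = 0.00239; adjusted p = 0.915 with an estimated correlation), with Myh11 at -0.55 and Tagln at -0.53, and lost the call without overexpressor control 2 (adjusted p = 0.0936). Without overexpressor control 1 the medians of these lists were -0.24 and -0.25, and without overexpressor control 3 that of smooth muscle was -0.68. Macrophage markers were lower in 19 of 21 (median -0.27) without a call (adjusted p = 0.239), with Cd68 at -0.27; the median was -0.040 and Cd68 at -0.015 without overexpressor control 1, and -0.48, with a call (adjusted p = 0.00229; adjusted p = 0.866 with an estimated correlation), and -0.53 without overexpressor control 3. The matrix mean per array overlapped between the groups, at -0.47, -0.42 and -0.24 in overexpressors and 0.29, 0.05 and -0.34 in controls. The interferon list was called higher (9 of 16 members, median 0.0045, adjusted p = 0.0357; adjusted p = 0.915 with an estimated correlation) since camera compares it with other genes and the median over all probe sets was -0.07; Cxcl9 was at 0.37 and Mx1 at -0.21. The interferon call ended without overexpressor 1 (adjusted p = 0.163), overexpressor 3 (0.223, median -0.015), overexpressor control 3 (0.274, median -0.088) or knockout 3 (0.0698), with quantile normalization (0.0502, median 0.088), with the lowest 60% of probe sets left out (0.258), with array weights (0.541) or gene-by-gene weights (0.353), without the 2 dimmest arrays (0.198) and on the line's own 6 arrays (0.0701). Of the 10 ways to divide these 6 arrays into 3 and 3, 7 called at least the 7 lists that the labels called.

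Among adipose genes fixed in advance, Lep (0.03), Adipoq (-0.05), Pparg (-0.07) and Ucp1 (-0.97) did not pass, nor did Rbp4, the retinol-binding protein secreted by fat (-0.49). Adipoq changed sign under quantile normalization (0.036) and median subtraction (0.013), and Pparg under quantile normalization (0.013). Without overexpressor 1, Adipoq (0.082) and Pparg (0.091) turned, Rbp4 was at -0.28 and Ucp1 at -0.41, and Lep turned without overexpressor control 1 (-0.14) or overexpressor 3 (-0.090). The nicotinamide list that holds Nnmt had 9 of 12 members lower (median -0.16, camera adjusted p = 0.286) and the retinoid list that holds Rbp4 had 8 of 11 higher (median 0.10, adjusted p = 0.0642), neither called by camera. In all, 7 of 37 lists were called with the preset correlation and 0 with an estimated one.

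**Figure D3:**
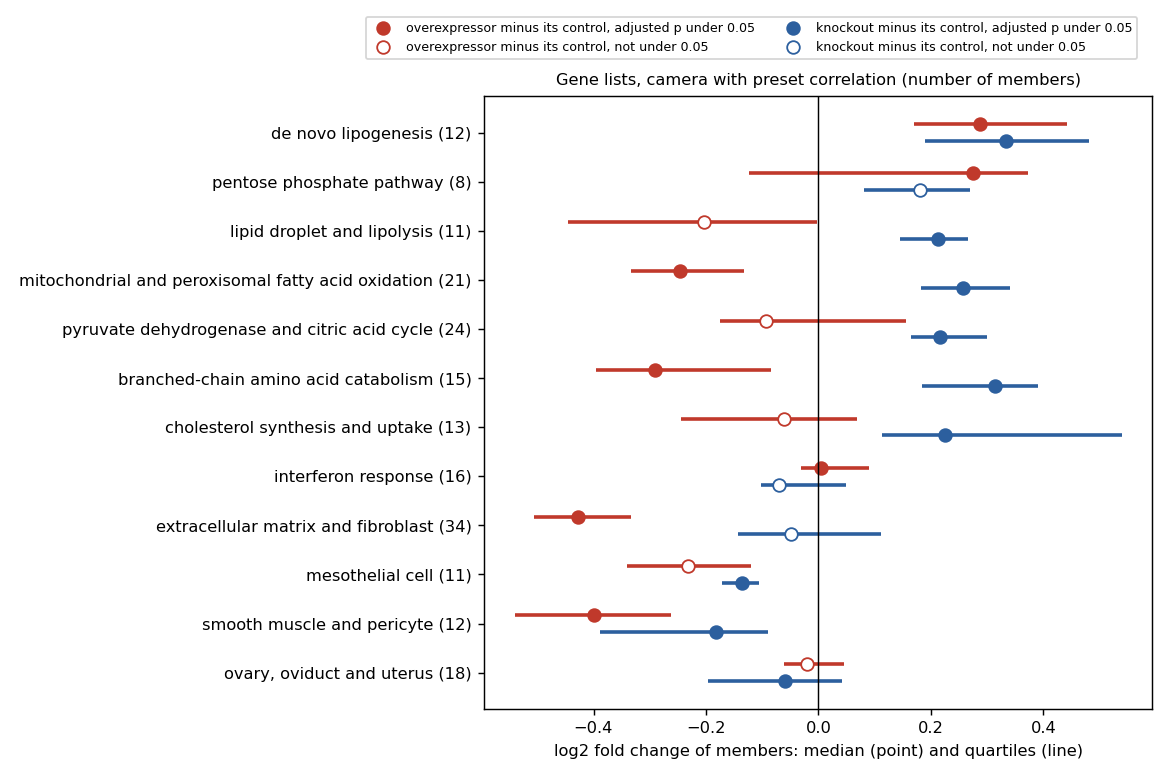
Median (point) and quartiles (line) of the log2 fold changes of the members of 12 lists, with the number of members in parentheses; filled points had a camera adjusted p under 0.05 with the preset correlation. Branched-chain amino acid breakdown and fatty acid oxidation lay below 0 in the overexpressor and above 0 in the knockout, and lipogenesis lay above 0 in both.

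The second comparison asked what loss of Glut4 from fat changed. Knockout fat had a higher signal of Serpina1b, Serpina1c and Serpina1e, whose family encodes alpha-1-antitrypsin, an inhibitor of serine proteases. Serpina1c read 1406 ± 432 against 280 ± 85.3 (log2 fold change 2.18, SE 0.25, limma adjusted p = 0.00314), Serpina1b 1267 ± 339 against 236 ± 93.7 (2.27) and Serpina1e 920 ± 272 against 186 ± 46.8 (2.08). All 7 tested probe sets of the family were called, from 1.69 to 2.33, but these paralogs share sequence and 3 of the probe sets name several of them, so they count as one signal. Ighm, the heavy chain of immunoglobulin M, rose from 701 ± 126 to 1911 ± 389 (1.40, SE 0.20, adjusted p = 0.0155). Pla2g12a, a secreted phospholipase A2, rose from 207 ± 57.7 to 643 ± 168 (1.48, SE 0.23, adjusted p = 0.0236).

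Other Ighm probe sets differed, at 1.14 (adjusted p = 0.0606), 0.01 and -0.80. The knockout had 9 called probe sets, all higher, and 7 of them were the Serpina1 family signal. An unadjusted p under 0.05 was found for 297 (258 higher, 39 lower), against 373 that chance gives. Over all probe sets the median log2 change in the knockout was 0.043. The lower genes with the smallest p, none of which passed, were Gpx3, the extracellular glutathione peroxidase (1864 against 3356, -0.85), Alpl (-0.49), Nkx2-6 (-0.39), Arf5 (-0.44) and Atp11a (-0.53). Gpx3 passed when adjusted over its list alone (adjusted p = 0.0403). The Serpina1b, Serpina1c and Serpina1e calls held whichever array was left out, but ended with the replicate number as a block. Ighm lost its call without knockout 2 (adjusted p = 0.105), knockout 3 (0.0636), knockout control 2 (0.101) or knockout control 3 (0.103), and Pla2g12a without knockout 2 (0.102), knockout 3 (0.161), knockout control 1 (0.0656), knockout control 3 (0.124) or overexpressor control 2 (0.0527). Pla2g12a was not called on the knockout line's own 6 arrays (adjusted p = 0.0675), nor were Ighm (0.0858) and Pla2g12a (0.159) without a filter on dim probe sets.

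Lists of lipid and mitochondrial metabolism lay higher in the knockout. Cholesterol synthesis was higher in 13 of 13 members (median 0.22, camera adjusted p = 0.000456; adjusted p = 0.816 with an estimated correlation); adjusted over the list alone, 2 passed, Nsdhl (0.90) and the lanosterol synthase Lss (0.54), with Fdps at 0.70 and Idi1 at 0.61. Branched-chain amino acid breakdown was higher in 14 of 15 (median 0.31, adjusted p = 0.000456; adjusted p = 0.816 with an estimated correlation), with Ivd at 0.43, Bcat2 at 0.44, Mmut at 0.38 and Auh at 0.30, none passing over the list alone. Fatty acid oxidation was higher in 20 of 21 (median 0.26, adjusted p = 0.000939; adjusted p = 0.816 with an estimated correlation), with Acadm at 0.40. The pyruvate dehydrogenase and citric acid cycle list was higher in 22 of 24 (median 0.22, adjusted p = 0.0116; adjusted p = 0.900 with an estimated correlation), with Idh2 at 0.40. Bcat2 was at 0.12 without knockout control 1 and 0.81 without knockout control 2. Without knockout 3 the branched-chain, fatty acid oxidation and citric acid cycle medians were 0.20, 0.15 and 0.12, without knockout control 2 the last 2 were 0.40 and 0.36, and the citric acid cycle median was 0.14 without knockout control 1 and 0.33 without knockout 1.

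Lipogenesis was higher in 12 of 12 (median 0.33, adjusted p = 0.0184; adjusted p = 0.816 with an estimated correlation), with Scd2 at 0.75, Acly at 0.50, Elovl6 at 0.38, Fasn at 0.23 and Scd1 at 0.08. Single arrays moved these values: without knockout control 1 the median was 0.19, Acly at 0.31, Elovl6 at 0.089 and Fasn at 0.032, and without knockout control 2 they were 0.59, 0.84, 0.70 and 0.48. Elovl6 and Fasn were at 0.062 and 0.12 without knockout 1 and at 0.78 and 0.37 without knockout 3, and Scd1 at 0.012 without knockout control 3. The lipid droplet list was higher in 11 of 11 (median 0.21, adjusted p = 0.0358; adjusted p = 0.816 with an estimated correlation), with Plin2 at 0.27. Without knockout control 1, the branched-chain, fatty acid oxidation, citric acid cycle, lipogenesis and lipid droplet lists were not called (adjusted p = 0.270, 0.399, 0.716, 0.661 and 0.716), and 3 lists were called in place of 9. Without knockout 3, fatty acid oxidation (0.225), the citric acid cycle (0.281) and lipid droplets (0.281) lost their calls, as did lipogenesis without knockout 1 (0.2499) or knockout 2 (0.0551) and lipid droplets without knockout 2 (0.0741), with a lipid droplet median of 0.13 without knockout 3, while cholesterol synthesis kept its call whichever array was left out. The lipogenesis call also ended without the 2 dimmest arrays (adjusted p = 0.0643) and the lipid droplet call with the lowest 60% of probe sets left out (0.05004).

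Called lower were smooth muscle markers (10 of 12, median -0.18, camera adjusted p = 0.00169), mesothelial markers (9 of 11, median -0.14, adjusted p = 0.00554) and the ovary, oviduct and uterus list (12 of 18, median -0.06, adjusted p = 0.0402). Each had an adjusted p = 0.816 with an estimated correlation, and among their members Tagln was at -0.38, Krt7 at -0.37 and Ovgp1 at 0.75. Their calls ended without knockout control 1 for smooth muscle (0.251), without knockout control 2 for mesothelium (0.0765), and without knockout 2, knockout 3, knockout control 1 or knockout control 3 for the ovary list (0.156 to 0.326). Without knockout control 1 the smooth muscle median was -0.056 and the ovary median 0.0090, and without knockout control 2 the mesothelial median was -0.071 and the ovary median -0.096. Without knockout control 3 the smooth muscle and mesothelial medians were -0.34 and -0.23, the smooth muscle median was -0.29 without knockout 3, the mesothelial median -0.085 without knockout 2, and the ovary median -0.031 without knockout 1 and -0.024 without knockout 2. The ovary call also ended with quantile normalization (median -0.11, adjusted p = 0.0771), median subtraction (-0.096, 0.0512) and array weights (-0.17, 0.0523), and the mesothelial call with the lowest 60% of probe sets left out (0.0875). Of the 10 ways to divide these 6 arrays, 4 called at least 9 lists. Adjusted over their list alone, Nnmt (0.57, adjusted p = 0.00923) and Aox1, which oxidises N-methylnicotinamide (0.49, adjusted p = 0.0109), were higher, and neither passed over all genes; their list was not called (8 of 12 higher, median 0.11, adjusted p = 0.313), nor was the retinoid list (7 of 11 higher, median 0.060, adjusted p = 0.243). Rbp4 (0.43), Lep (0.50), Adipoq (0.06), Pparg (0.32), Ucp1 (1.28), Cd68 (0.22), Pck1 (-0.08) and Cyp2e1 (0.06) did not pass, and Adipoq changed sign with quantile normalization (-0.012). Without knockout control 1, Ucp1 was at 0.088, Cyp2e1 at -0.060 and Cd68 at 0.42, and without knockout control 2 Ucp1 was at 2.02, Cyp2e1 at 0.16, Cd68 at 0.051, Lep at 0.29 and Adipoq at 0.11. Without knockout control 3 Adipoq was at 0.019 and Pck1 at -0.026, without knockout 1 Pck1 was at -0.015, without knockout 2 Cyp2e1 was at 0.042, and without knockout 3 Pparg was at 0.20, Adipoq at 0.028 and Pck1 at -0.15.

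Whether the effects of gain and loss differ was tested directly, each effect taken against its own control. Gain and loss came from lines that also differ in background, kind of control and array set. A difference therefore cannot be ascribed to Glut4 alone. Nnmt had the difference with the smallest p: overexpression minus knockout was -1.94 on the log2 scale (limma adjusted p = 0.00109). The difference also passed for Cyp2e1 (-1.58), Oxct1 (-1.53), Hsd11b1 (2.15), 1 Mmp12 probe set (1.17) and the 7 Serpina1 family probe sets (-3.05 to -2.00). In all 12 probe sets passed (2 higher, 10 lower), and 370 had an unadjusted p under 0.05, against 373 that chance gives. Over all probe sets the median difference was -0.12, and 0.01 after quantile normalization. Nnmt kept this call whichever array was left out. Cyp2e1 lost it without knockout 2 or knockout 3, Serpina1e without knockout 3, Serpina1c without any of 4 arrays, Hsd11b1 and Serpina1b without any of 9 and Oxct1 without any of 11. The count was 1 without knockout 3, 4 without knockout 2, 5 without overexpressor 3 and 6 without knockout control 3, and without a filter on dim probe sets it was 1, Nnmt. With overexpressor 1 and overexpressor control 3 each counted in the other's group, the difference called 0 probe sets, so these calls rest on the labels of those arrays.

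By list, branched-chain amino acid breakdown (median difference -0.54, camera adjusted p = 6.57e-06), fatty acid oxidation (-0.48, 0.000161), cholesterol synthesis (-0.43, 0.0148), matrix and fibroblast (-0.39, 0.0148) and lipid droplet (-0.33, 0.0148) lists had lower effects in the overexpressor than in the knockout. The interferon (0.067, 0.00458) and ovary (0.0022, 0.0323) lists were called higher, as camera compares a list with other genes. Over all probe sets the median difference was -0.12, so these calls do not by themselves show a higher effect in the overexpressor. With an estimated correlation none of the 7 list calls held (smallest adjusted p = 0.995). Leaving out 1 array ended the calls of matrix (overexpressor control 1, with a median of -0.21 and camera adjusted p = 0.222, overexpressor control 2, 0.0739, overexpressor 2, 0.169, knockout 3, 0.395, or knockout control 2, 0.185), cholesterol synthesis (overexpressor 1, 0.0870, overexpressor control 3, 0.282, or knockout 1, 0.0700) and lipid droplets (overexpressor control 3, 0.191, knockout 3, 0.0761, or knockout control 1, 0.219). The ovary call ended without overexpressor 1, overexpressor control 3, knockout 2 or 3 or knockout control 1 or 3 (0.0512 to 0.254), and its median lay below 0 without any of these but knockout 3, while the other 3 lists kept their calls whichever array was left out, the interferon median being -0.019 without knockout control 2 and -0.0063 without overexpressor control 3. With quantile normalization the medians of fatty acid oxidation, matrix, lipid droplets, interferon and ovary were -0.33, -0.24, -0.17, 0.18 and 0.15, and the ovary call ended (adjusted p = 0.0774). With the lowest 60% of probe sets left out the cholesterol, matrix, interferon and ovary calls ended (0.0619 for each). Array weights ended the calls of cholesterol synthesis (median -0.19, adjusted p = 0.285), interferon (0.121) and ovary (0.385), as did weights fitted gene by gene (0.117, 0.0558 and 0.300), and gave -0.23 for matrix. Without the 2 dimmest arrays the fatty acid oxidation, cholesterol and lipid droplet medians were -0.25, -0.28 and -0.22 and the interferon (0.0812) and ovary (0.724) calls ended, and the ovary call also ended without a filter on dim probe sets (0.0593). Fry's directional test, the one planned, called 0 lists in all 3 contrasts (smallest adjusted p = 0.647, 0.790 and 0.563). Its mixed test, which takes no account of direction, called 4, each holding 1 called gene: the nicotinamide list with Nnmt (adjusted p = 2.24e-05) and glycerolipid synthesis with Pck1 (0.00599) in the overexpressor, B cell markers with Ighm (0.0111) in the knockout and the nicotinamide list again (6.21e-05) in the difference.

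No probe set passed the adjusted threshold in both comparisons, by limma, so none was shown to move in opposite directions. At unadjusted p under 0.05 in both, 20 were lower in the overexpressor and higher in the knockout, against 9.10 for independent lists, and 2 went the other way, against 0.481; 1 was higher in both, against 3.18, and 2 were lower in both, against 1.38. These expectations hold for independent probe sets only: of 100 drawn splits of the arrays, 22 gave at least 22 opposite probe sets, and the highest gave 378. By the smaller of the paired changes, Wfdc21 came first among the 20 (-1.12 and 0.90). Next were probe sets of the Serpina1 family (-0.78 and 2.21, and -0.73 and 2.33), which count as one signal. The 20 also include Nnmt (-1.37 and 0.57), Oxct1 (-1.09 and 0.45), Rbp4 (-0.49 and 0.43), Ivd (-0.59 and 0.43) and Tshr (-0.48 and 0.50). Nnmt, Rbp4 and Ivd are on lists chosen with knowledge of reports on these lines. Across all 7454 probe sets, which are not independent replicates, the log2 fold changes had Pearson r = -0.00444 and Spearman rho = -0.00817; without overexpressor 1 r was 0.20, and with that array and overexpressor control 3 each counted in the other's group it was 0.446.

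**Figure D4:**
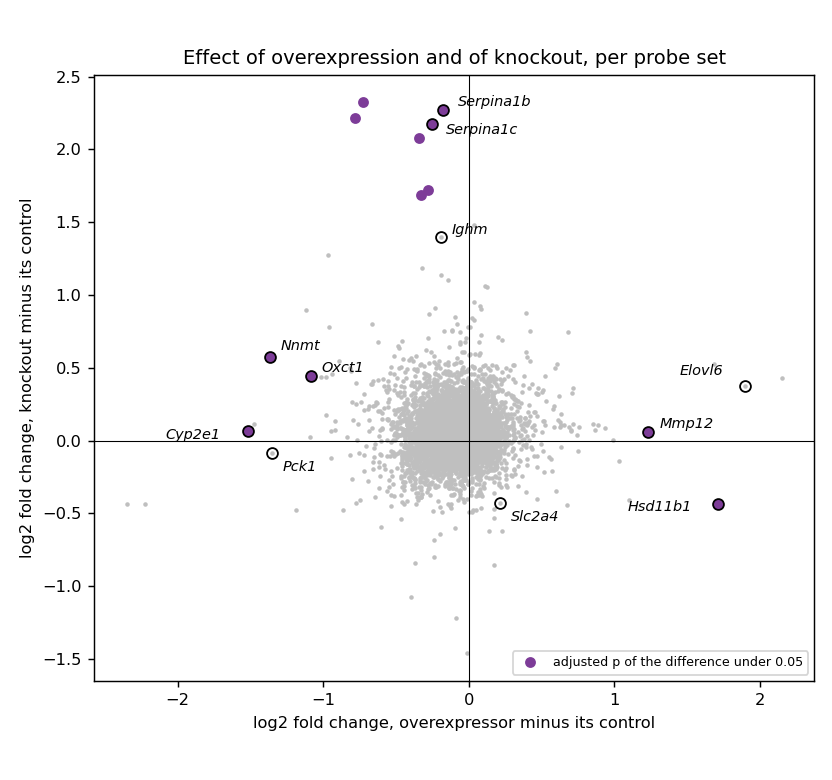
Log2 fold change of each tested probe set in the overexpressor (horizontal axis) against the knockout (vertical axis), each against its own control; purple points had an adjusted p of the difference under 0.05. Nnmt and Oxct1 lay at negative overexpressor and positive knockout values, and the cloud as a whole had r = -0.00444.

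**Figure D5:**
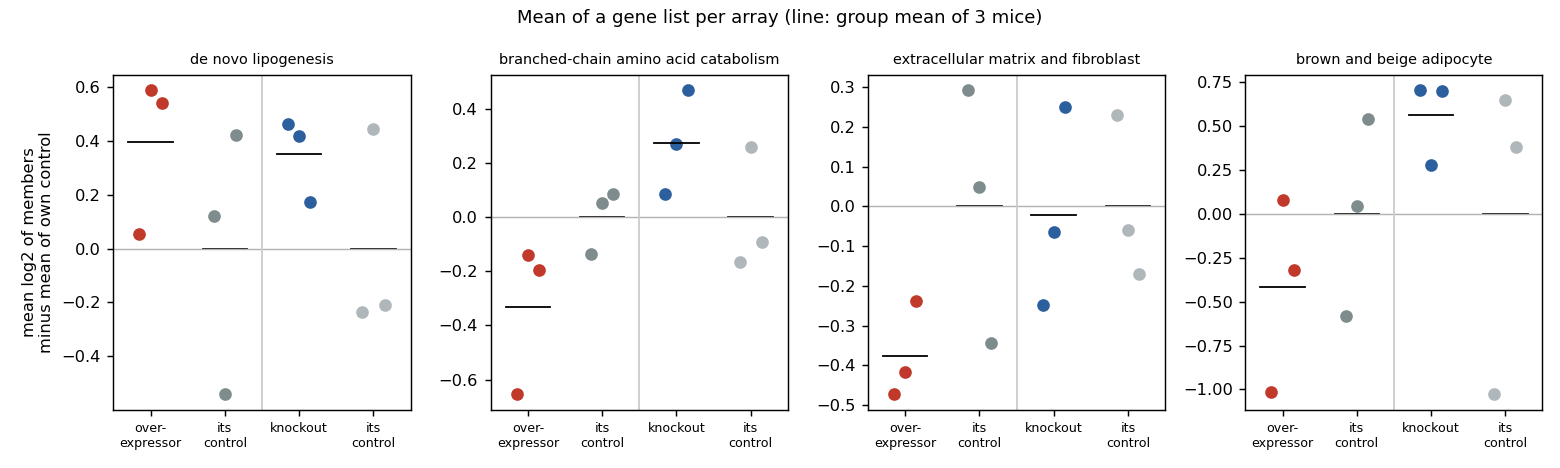
Mean log2 intensity of the members of 4 lists on each array, minus the mean of that line's own control group, with a line at each group's mean. Arrays of a group lay far apart, for example at 0.12, -0.54 and 0.42 for lipogenesis in overexpressor controls and at -1.03, 0.65 and 0.38 for brown and beige adipocyte genes in knockout controls.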

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

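The tests of liver genes, of B cell markers, of adipocyte genes, of the fit without overexpressor 1, of an exchange of arrays, of an unread transgene and of the size of the correlation across probe sets were chosen only after the result was seen.

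Serpina1 family probe sets and Ighm were higher in knockout fat. RNA from liver would need the abundant liver genes to rise by a median of at least 1.09 (the Serpina1 median divided by 2); the 10 of 23 listed genes that were tested had a median of -0.022 (upper quartile 0.075), with Alb at 0.13 and Apoa1 at -0.041. More B cells would need other B cell markers to rise by at least 0.70, and 9 of them had a median of -0.060 (upper quartile 0.0075). A chromosome segment of another strain in the mixed background stays open and may act on these genes, since 3 of 54 tested neighbours (5.56%) had an unadjusted p under 0.05, between the median (3.70%) and the 95th percentile (9.26%) of random windows. Sequence shared between Serpina1 paralogs makes their 7 probe sets 1 signal, and an effect of losing Glut4 stays open and untested.

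Nnmt, Cyp2e1 and Pck1 were lower in the overexpressor, with a median change of -1.37. A lower share of adipocytes would need adipocyte genes to fall by at least 0.68 in the middle, and 14 of 18 listed genes had a median of -0.035 (lower quartile -0.065). The low brightness of overexpressor 1 was tested by leaving that array out, after which the median change was -1.33 and the largest adjusted p of the 3 genes 0.0200, by limma. An effect of Glut4 overexpression is a hypothesis that these tests leave open, as are differences between the mice, such as litters or recent feeding, that the labels do not give.

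The main fit detected no rise of Slc2a4 on the arrays labelled overexpressor (0.22), while the planned array weights, whose iteration did not converge, called one. The probe set may not read the transgene, and no value here can decide that. An exchange of labels between overexpressor 1 and overexpressor control 3 could hide a rise: regrouped that way, 7 probe sets were called, the most of 9 regroupings, against 6 by the labels, but Slc2a4 among them tests nothing, as the regrouping moves the lowest overexpressor and the highest control reading of that gene. The criterion written first, that a regrouping calls more probe sets than the labels do, was met by 7 against 6. It was changed after that was seen, to require also that the labels call none, which their 6 calls had already made impossible. The reason given was that Nnmt, Cyp2e1 and Pck1 separate the groups completely by the labels. These genes were picked by the same labels, so their separation is no evidence for them. Of 7454 tested probe sets, 656 (8.80%) separated these groups completely. Overexpressor control 3 was closer to the overexpressors than to its own group (mean correlation 0.971 against 0.954) and overexpressor 1 to its own group than to the controls (0.959 against 0.949), so an exchange and correct labels cannot be told apart, and the overexpressor comparison and the calls of the difference rest on the labels: regrouped that way, the difference called 0 probe sets against 12, and the correlation across probe sets was 0.446 against -0.00444.

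For the number of called probe sets, 10 splits of 6 arrays are too few for a share under 0.05. In the overexpressor line the labels gave 6 and the highest other split 7 (2 of 10 as large), and in the knockout line 9 and 4 (1 of 10). For lists, the overexpressor labels gave 7 and the highest other split 17 (7 of 10 as large), and the knockout labels 9 and 14 (4 of 10). For the difference between the effects, 3 of 100 splits, the labels among them, called at least the 12 probe sets of the labels. The splits regroup both lines at once, so a change in 1 line alone can give such a share. It therefore does not exclude chance for a difference between the effects. The highest other split called 96, which points to a structure of the samples, though no test here tells that from genes that vary together. It set overexpressor 1, overexpressor 3 and overexpressor control 3 against the rest of their line, and knockout 3, knockout control 1 and knockout control 2 against the rest of theirs. The other split above the labels called 35 and kept the knockout labels, with overexpressor 1, overexpressor control 1 and overexpressor control 2 against overexpressor 2, overexpressor 3 and overexpressor control 3; the same arrays with the sides in the order of an exchange called 0. Chance was not excluded for the 22 opposite probe sets at unadjusted p (22 of 100 splits as large, highest other 378), the 7 lists of the difference (55 of 100, highest other 19) or the size of the correlation, 0.00444 (99 of 100, highest other 0.539).

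These results drew attention because the test of the difference between the overexpressor and knockout effects passed. Background, kind of control and array set differ along with gain and loss, so their parts in these differences cannot be told apart. Among genes, the difference on the log2 scale was -1.94 for Nnmt, -1.58 for Cyp2e1, -1.53 for Oxct1, 1.17 for Mmp12 and 2.15 for Hsd11b1. For the Serpina1 family it was -2.45 for Serpina1b, -3.05 and -2.43 for the probe sets of Serpina1c, -2.42 for Serpina1e, and -2.01, -3.00 and -2.00 for 3 probe sets that name several members. Among lists, the median difference was -0.54 for branched-chain amino acid breakdown, -0.48 for fatty acid oxidation, -0.43 for cholesterol synthesis, -0.39 for matrix and fibroblast genes, -0.33 for lipid droplets, 0.067 for the interferon response and 0.0022 for ovary, oviduct and uterus, and none of these list calls held with an estimated correlation. The interferon and ovary lists were called relative to other genes, the median difference over all probe sets being -0.12.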

How the results depend on the processing

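Array weights fitted gene by gene and the fit without the 2 dimmest arrays (overexpressor 1 and knockout control 3) were chosen after seeing the data. The cause of the changes given here was not tested, except where fewer probe sets or arrays entered a fit. For comparison, limma called 6, 9 and 12 probe sets in the overexpressor, the knockout and the difference, camera called 7, 9 and 7 lists, and 22 probe sets were opposite at unadjusted p with r = -0.00444.

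Quantile normalization called 12 in the overexpressor and median subtraction 11. Without a filter on dim probe sets the difference called 1, and 35 were opposite at unadjusted p. With the lowest 60% left out the difference called 3 lists. Planned array weights, whose iteration did not converge, called 411, 15 and 44, with 2 opposite at adjusted p, 64 opposite at unadjusted p, r = 0.295 and Slc2a4 called at 0.69 in the overexpressor. Gene-by-gene weights called 67, 14 and 25, with 42 opposite and r = 0.273, and Slc2a4 at 0.61 was not called (adjusted p = 0.138). The overexpressor's own 6 arrays called 1. An adjusted p under 0.10 called 13 in the overexpressor. An unadjusted p under 0.05 called 355, 297 and 370, against 373 that chance gives for each, with 22 opposite. With 1 probe set per gene 5 were called in the knockout and 7 in the difference, since fewer probe sets were tested. An estimated correlation and fry's directional test called 0, 0 and 0 lists. Without the 2 dimmest arrays the comparisons called 8, 8 and 1, with 11 opposite and r = 0.206.

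With the replicate number as a block, 5, 0 and 1 probe sets were called. The numbers gave no sign of pairing the mice: correlations of same-numbered arrays were -0.06, -0.09 and 0.02 in the overexpressor line and -0.24, -0.04 and -0.36 in the knockout line, and no array correlated best with its own number. With so few arrays per group these correlations cannot exclude a pairing. Whether the calls lost under the block are weaker effects therefore stays open.

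Leaving out each array in turn gave 3 (without overexpressor control 2) to 21 (without overexpressor control 3) calls in the overexpressor, 6 to 11 in the knockout and 1 (without knockout 3) to 13 in the difference, with 4 without knockout 2, 5 without overexpressor 3 and 6 without knockout control 3. Opposite probe sets at unadjusted p numbered 10 (without knockout 2) to 37 (without knockout 1), with 13 without knockout 3 or knockout control 3 and 14 without overexpressor control 3. The correlation ran from -0.12 (without knockout 1) to 0.20 (without overexpressor 1), with 0.12 without overexpressor control 3 and 0.15 without knockout 3. Called lists ran from 3 (without overexpressor control 2) to 11 (without overexpressor control 1 or 3) in the overexpressor, 3 (without knockout control 1) to 13 in the knockout and 4 (without knockout 3) to 11 (without overexpressor control 1) in the difference. Slc2a4 ran from 0.026 to 0.53 in the overexpressor and from -0.56 to -0.30 in the knockout, called in none of these fits.

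Direction reversed, never past the threshold, for Adipoq in the overexpressor (quantile 0.036, medians 0.013, without the 2 dimmest arrays 0.082, leaving out an array -0.13 to 0.082), Pparg in the overexpressor (quantile 0.013, without the 2 dimmest arrays 0.091, leaving out an array -0.27 to 0.13), Adipoq in the knockout (quantile -0.012), Lep in the overexpressor (leaving out an array -0.14 to 0.23) and Cyp2e1 in the knockout (leaving out an array -0.060 to 0.16). Over all named genes and alternatives, 1704 values kept direction and side of the threshold, 89 lost the threshold, 31 gained it and 13 reversed. Values not called in the main fit kept their side by staying uncalled, so the 1704 do not measure how stable the calls were. Without a filter on dim probe sets 10 gene values lost the threshold, and with the block 12 did. Of list values, all called in the main fit, 474 kept and 140 lost it. Signal over background limits dim genes, with 4968 probe sets not tested.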

Other observations

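The test of lipogenic covariation against random lists and the tests of uncalled lists with 1 array left out were chosen only after the result was seen; the test of lipogenic genes against Pck1 was planned.

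Genes of oxidative phosphorylation were not called, and their direction in the overexpressor turned with 1 array. Of 51 members, 45 were lower in the overexpressor (median -0.13, camera adjusted p = 0.445) and 45 higher in the knockout (median 0.14, adjusted p = 0.0762), and the difference was negative for 49 (median -0.26, adjusted p = 0.0969; adjusted p = 0.996 with an estimated correlation). The array means, less that of the controls, were -0.51, 0.15 and -0.0083 in overexpressors and -0.044, -0.077 and 0.12 in their controls. Without overexpressor 1, the dim array, 40 of 51 members were higher (median 0.078, adjusted p = 0.0369; adjusted p = 0.892 with an estimated correlation) and the median difference was -0.064. Without overexpressor 2, 50 were lower (median -0.27, adjusted p = 0.000384; adjusted p = 0.939 with an estimated correlation). The knockout median was 0.032 without knockout 3 (adjusted p = 0.945) and 0.30 without knockout control 2 (adjusted p = 5.64e-06; adjusted p = 0.744 with an estimated correlation). Brown and beige adipocyte genes were lower in 6 of 7 in the overexpressor (median -0.31, adjusted p = 0.673) and higher in 6 of 7 in the knockout (median 0.55, adjusted p = 0.152), also without a call; the medians were -0.086 without overexpressor 1, -0.041 without overexpressor control 3 and, in the knockout, 0.088 without knockout control 1. Ucp1, the uncoupling protein of brown fat, read 1452, 711 and 1159 in knockouts and 50.4, 1232 and 808 in their controls, so knockout control 1 alone lay apart. Adipogenic transcription factors were lower in 15 of 15 members in the overexpressor (median -0.09, adjusted p = 0.272) and in 10 of 15 without overexpressor 1 or overexpressor control 2. Over all probe sets the median change was -0.072 in the overexpressor and 0.043 in the knockout. Counts of members below or above 0 therefore do not by themselves show that a list changed.

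Xist, the transcript of the inactive X chromosome, read 86.5 on knockout control 3 and 293.3 to 560.4 on the other 11 arrays, all labelled female. On the same array the Y-linked genes Kdm5d and Uty read 80.0 and 57.5, against at most 76.0 and 46.8 on the other arrays, and Eif2s3y read 22.8, its lowest value. The Y-linked probe sets lie near the floor, so the sex of this mouse is not settled here. Its array is a control of the knockout comparison and enters the difference, and fits without it are given above.

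The 12 tested lipogenic genes varied together between mice of the same group, with a mean within-group correlation of 0.638, at the 99.8th percentile of 10000 random lists matched on intensity (median 0.270, 95th percentile 0.502). The test was chosen after this covariation was seen, so the percentile describes it and does not exclude a chance set of genes. Such covariation was not particular to lipogenesis, as the same measure was 0.765 for oxidative phosphorylation, 0.701 for brown and beige adipocyte genes, 0.661 for fatty acid oxidation and 0.655 for the citric acid cycle. A hypothesis is that the mice may have differed in recent feeding, in which case Pck1, a gene that is higher in fasting, would go against the list. Over 12 arrays the deviations of the list mean and of Pck1 from their group means had Pearson r = -0.071 (permutation p = 0.915) and Spearman rho = 0.021 (permutation p = 0.968), over 1296 permutations within groups. Without the 2 arrays farthest from the median r was -0.030, and it was 0.036 in the overexpressor line and -0.45 in the knockout line; the test decides neither way, as 1 gene is a weak measure of feeding.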
